A study of Rattus norvegicus with 8 samples.

How the data were processed

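RNA from 8 samples of the rat PC12 line Htt14A2.5 was measured on 8 Affymetrix arrays of 8799 probe sets, with 1 array per sample. PC12 is a line from a rat adrenal medullary tumour. Per the labels, the line carries an inducible, truncated mutant form of the first exon of human huntingtin. The labels also name the inducer, ponasterone (a steroid), given for 48 h. Such systems commonly use an ecdysone receptor that works with the mammalian receptor RXR; the parts of this system are not given in the sources used here. The titles give 4 induced and 4 uninduced samples, each group numbered 1 to 4, and these titles set the groups. The free-text descriptions of all 8 samples mention induction, so they do not tell the groups apart. The sources used here do not say whether the replicates were separate cultures grown on separate days.

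The deposited values are intensities, 1 scaled signal per probe set and array, linear and above 0. Each of the 8 arrays had a trimmed mean between 500.8 and 500.9 (2% trimmed from each end), so the authors had scaled the arrays to a common level before they deposited them. The program and any earlier steps are not given in the sources used here. The table holds no detection calls, so whether a transcript was detected is unknown. As a reference for low signal, 38 control probe sets for bacterial, yeast or mouse sequences or the reverse strand were read on each array; their 95th percentile lay between 102 and 183. For arrays, the number of arrays limits the precision.

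Gene symbols came from an annotation table of this array. It gave 1 symbol for 7018 probe sets, several for 308 and none for 1473. Of the 7018, 6994 had a gene identifier found in the rat reference list (assembly GRCr8), with the same symbol; no coordinates were used. A symbol says which gene the annotation assigns, and a probe set can also bind transcripts of close relatives.

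The signals were transformed to log2 after adding 7, the rounded 10th percentile of all values. The 59 control probe sets were left out. So were the 2611 others with a mean over the 8 arrays under the 30th percentile (a signal of 36.0), which left 6129 probe sets for 3623 genes. Induced minus uninduced differences were fitted with limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with an intensity trend), with Benjamini-Hochberg adjustment over the 6129 probe sets and a threshold of 0.05 on the adjusted p. Errors of log2 differences are standard errors of this fit, which had 6 residual and 5.77 prior degrees of freedom; errors of signals are SDs. Folds are computed from the fitted log2 differences and therefore include the added 7. On simulated arrays of 6129 probe sets with 200 changed, the fit recovered 60% of changes of log2 size 1 and 93% of those of size 2. Of its 161 calls 8 were false, and it made 0 calls when nothing was changed. The simulation drew each probe set independently, so it does not show how many false calls arise where probe sets vary together.

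Before the data were examined, 25 gene lists were fixed, among them heat shock proteins, the unfolded protein response, the proteasome, cholesterol synthesis, fatty acid synthesis, catecholamine synthesis, dense-core granules, synaptic vesicles, targets of the RE1 silencing factor (REST), CREB and immediate early genes, voltage-gated channels, neurotransmitter receptors, p53 targets, the cell cycle, oxidative phosphorylation, glycolysis and hypoxia, oxidative stress, targets of the RXR partner receptors, interferon response, ribosomal proteins, and markers of fibroblasts, Schwann cells and glia, leukocytes and adrenal cortex. Each gene was represented by the probe set with the highest mean signal. Lists with at least 5 measured genes were tested with limma's camera (preset correlation between genes of 0.01), again with an estimated correlation, and with fry, with adjustment over the 24 lists tested. Adrenal cortex markers had 4 measured genes and were not tested. Counts of called members are given over all probe sets and adjusted over the list alone. The directional test of fry asks whether a list's genes move one way on balance, and neither fry test compares a list with other genes.

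The named genes were set by a rule fixed at the same time. It takes the 12 largest rises and 12 largest falls among called probe sets with 1 symbol and no overlap between the groups, with 1 probe set per gene (the lowest p), the 4 members of each list with the lowest p, and Htt, Bdnf, Th, Hspa5, Hspa8, Hspa1b, Ddit3, Npy, Chga, Vgf, Syn1, Snap25, Rest, Actb and Gapdh. Hspa8, Hspa1b and Chga had no probe set with a single symbol. Rest lay below the low-signal filter, and the probe sets assigned to Gapdh alone were controls. Other genes named were chosen after their values were seen. One fixed list and one gene of the rule are not reported here; numbers of lists fixed, tested or passing include that list.

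RNA quality was described by the log2 ratio of the 3' to the 5' control signal of Gapdh, beta-actin and hexokinase, compared with exact two-sided permutation tests (smallest possible p = 0.0286). The alternatives were other added constants (1 and 28), other filters (none, or the 50th percentile), quantile normalization, median centring, other moderation, an ordinary unmoderated test, the replicate number as a block, leaving out each array, leaving out replicate 2 of both groups, whose source label is worded differently, an estimated correlation, and the mean of a gene's probe sets. The wording of that label as a covariate was added after the data were seen. Every split of the 8 arrays into 4 and 4 (35 splits) was refitted. Figures were drawn with matplotlib 3.10.9.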

Results

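Transcript levels were compared between 4 samples of the PC12 line Htt14A2.5 induced with ponasterone for 48 h and 4 uninduced samples of the same line. The question, as the series title gives it, is which transcripts differ between the induced and the uninduced state. Each sample was measured on 1 array as a scaled signal per probe set. The median signal of the 8 arrays lay between 97.5 and 134.9, and Spearman correlations between arrays ranged from 0.945 to 0.967 across probe sets, which are not independent replicates. The first principal component (25.5% of the variance) spread the arrays of both groups, from -19.6 (uninduced replicate 3) to 34.5 (induced replicate 4, the next at 12.8). Arrays with negative scores all had lower median signals than those with positive scores. The second component (23.5%) separated the groups. The limma and permutation p-values here measure the spread between these samples, and the labels do not say whether they were separate cultures. A camera p compares a list's genes with other genes, so its size does not measure the spread between samples.

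Induced cells had higher transcripts of several immediate early genes and of chaperones and regulators of the unfolded protein response. Vgf, a secreted neuropeptide precursor, rose 6.67-fold, and Plaur, the urokinase receptor, rose from a signal near background. Of 33 measured cell cycle genes 13 fell, among them Pold1, Top2a and Cdk1. In all, 433 of 6129 probe sets (7.06%) passed the limma test, 251 higher and 182 lower after induction. They represented 166 genes that rose and 122 that fell, with no gene in both directions. Among the calls, 82 were at least 2-fold higher and 30 at least 2-fold lower. At an unadjusted p under 0.05 there were 1105 probe sets, where 306 would be reached by chance. The 2 groups did not overlap in 426 of the 433 calls, and in 13.6% of all tested probe sets against 2.86% by chance. Median centring of the arrays called 230 (167 higher and 63 lower, 72.6% higher against 58.0%), and leaving out replicate 2 of both groups, whose source label is worded differently, called 221 (141 higher and 80 lower, 218 of them among the 433). The count of lower probe sets was 119 without uninduced replicate 2 and 112 without uninduced replicate 3.

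The largest rise was that of Csrp3, a LIM-domain protein known from striated muscle, from a signal of 50.5 ± 56.5 in uninduced cells to 1314 ± 79.5 in induced cells (SD, n = 4 each), a log2 difference of 4.93 ± 0.44 (limma adjusted p = 2.5e-05). Plaur rose from 89.98 ± 32.6 to 1470 ± 125 (log2 difference 3.99 ± 0.22, adjusted p = 9.0e-07). Fosl1, a partner of Jun in the AP-1 transcription factor, rose by 3.54 ± 0.30, and Hbegf, a ligand of the EGF receptor, by 2.92 ± 0.21. Vgf had the lowest p of all probe sets, with 1398 ± 143 in uninduced and 9349 ± 729 in induced cells (log2 difference 2.74 ± 0.10, adjusted p = 2.9e-08). Flnc, an actin crosslinker, rose by 2.68 ± 0.11, and its second probe set by 1.73. Lama5, a laminin chain, rose by 2.59 ± 0.32, and the zinc finger factor Egr1 by 2.46 ± 0.16, with other Egr1 probe sets at 1.83 and 1.76 and 1 at 0.28 that did not pass. Dusp1, a phosphatase of MAP kinases, rose by 2.43 ± 0.15. Gdf15, a secreted stress-responsive cytokine, rose by 2.41 ± 0.31, Klf6 by 2.32 ± 0.30 and Ifrd1 by 2.28 ± 0.18. The uninduced signals of Csrp3, Plaur, Fosl1, Lama5 and Klf6 averaged 47.1 to 89.98, under the 95th percentile of the background controls on every array (102 to 183), and among these 12 genes only those of Vgf and Flnc averaged above that range. The sizes and ranks of the other 10 rises therefore depend on the background and the constant added: Csrp3 ranged from 4.31 to 5.50 and Plaur from 3.70 to 4.18 over the alternatives. That all 4 induced arrays lay above all 4 uninduced arrays for each of these 12 genes follows from the rule that named them.

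**Figure D1:**
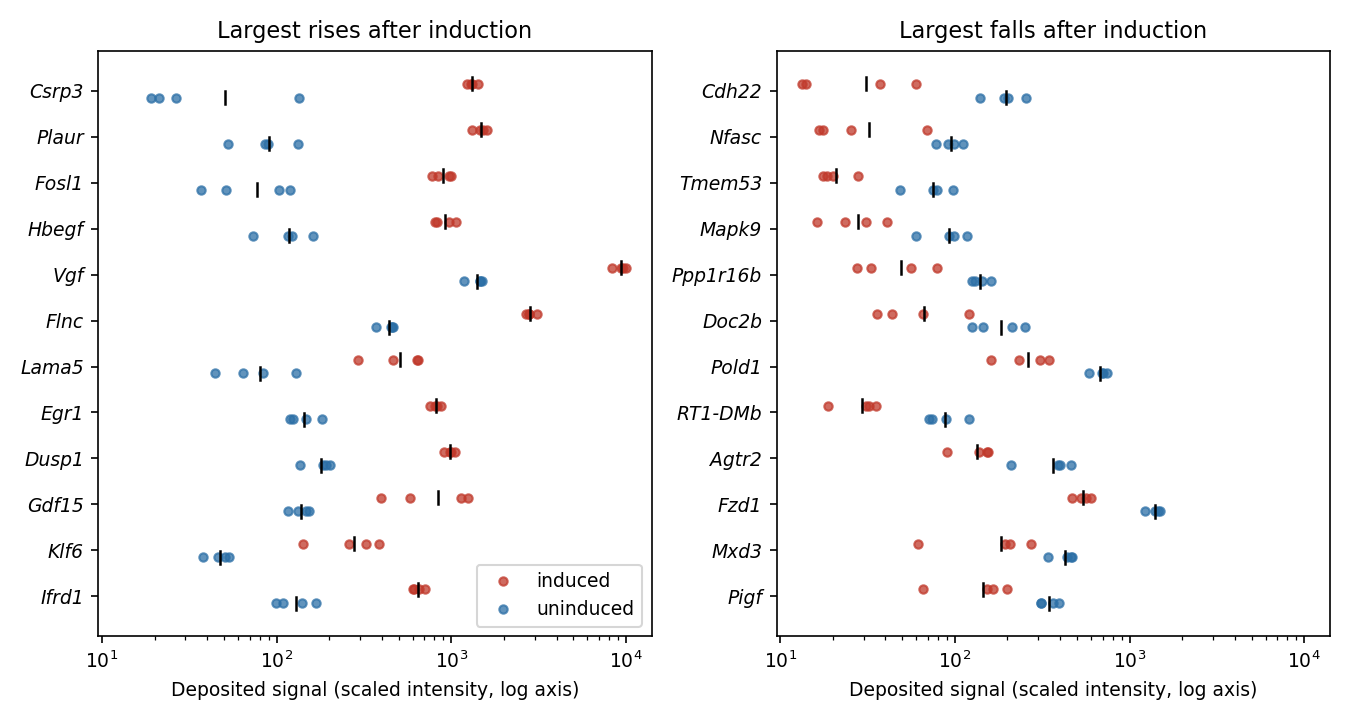
Deposited signal (log axis) of the 12 genes with the largest rise (left) and the 12 with the largest fall (right) after induction; each point is 1 of 4 arrays per group and each vertical line a group mean. The induced arrays of Vgf average 9349 against 1398 in uninduced cells, and most of the falling genes had low signals.

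The largest falls had smaller log2 differences than the largest rises. Low signals in many of both keep these sizes from a direct comparison. Cdh22, a cadherin, fell by 2.58 ± 0.41 on the log2 scale, from 197 ± 48.1 to 31.2 ± 22.2 (SD, n = 4 each; limma adjusted p = 0.0020), while a second Cdh22 probe set differed by 0.38 (adjusted p = 0.74). Pold1, the catalytic subunit of DNA polymerase delta, fell by 1.41 ± 0.21, from 681 ± 67.6 to 262 ± 82.5. Fzd1, a receptor for Wnt proteins, fell by 1.36 ± 0.12, from 1392 ± 121 to 541 ± 58.7 (adjusted p = 2.1e-05). Agtr2, an angiotensin receptor, fell by 1.38 ± 0.26, and a second probe set fell by 2.34. Nfasc fell by 1.55, Tmem53 by 1.52, Mapk9 by 1.52, Ppp1r16b by 1.48, Doc2b by 1.46, RT1-DMb by 1.39, Mxd3 by 1.35 and Pigf by 1.30. The induced signals of Cdh22, Nfasc, Tmem53, Mapk9, Ppp1r16b, Doc2b and RT1-DMb averaged 21.0 to 66.5, under the 95th percentile of the background controls on every array. The sizes of these falls depend on the background and the constant added, and Cdh22 ranged from -2.91 to -1.98 over the alternatives. The other probe sets of Mapk9 differed by 0.15 and 0.16, those of RT1-DMb by 0.14 and 1.00, that of Pigf by -0.10 and that of Nfasc by -0.54, and none of these passed. Only Cdh22, Pold1 and Fzd1 of the 12 passed under every alternative in which they were tested. Of the 8 fits that each left out 1 array, Nfasc passed in 1, Doc2b, Mxd3 and RT1-DMb in 2, Tmem53 and Mapk9 in 3, and Ppp1r16b and Pigf in 7 (highest adjusted p 0.137, for Nfasc without uninduced replicate 3). Without uninduced replicate 2 the adjusted p was 0.114 for Mapk9, 0.112 for Mxd3 and 0.0511 for Pigf. Without uninduced replicate 3 it was 0.109 for Doc2b, 0.0936 for Tmem53 and 0.0594 for Ppp1r16b, and without uninduced replicate 4 it was 0.0881 for RT1-DMb. Agtr2 passed in all 8 of these fits, and not without replicate 2 of both groups (adjusted p = 0.0695).

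Cell cycle genes were lower after induction. Of 33 measured members 13 fell, 0 rose and 20 were not called; adjusted over the list alone, 19 fell and 1 rose. Top2a, a topoisomerase of dividing cells, fell by 0.94 ± 0.10, Cdk1, the mitotic kinase, by 0.79 ± 0.09, Mcm7, a subunit of the replicative helicase, by 0.77 ± 0.10, and Pold1 by 1.41. The list's median log2 difference was -0.42, and it passed camera (adjusted p = 3.4e-12, and adjusted p = 0.0211 with an estimated correlation).

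The CREB and immediate early list was higher, with 10 of 33 members up, 1 down and 22 not called; adjusted over the list alone, 11 rose and 1 fell. Dusp1 rose by 2.43, Jun by 2.22 ± 0.14, Fosl1 by 3.54, and Egr1, represented by another probe set, by 1.83 ± 0.12. The member that fell was the mitotic kinase Plk1, which the cell cycle list also holds and which was chosen after its values were seen. The median was 0.29 (camera adjusted p = 1.2e-07, and adjusted p = 0.0121 with an estimated correlation). Fos differed by 0.29 (adjusted p = 0.285), a value looked up after the others were seen.

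The unfolded protein response and ER chaperone list was higher, with 6 of 18 members up, 0 down and 12 not called; adjusted over the list alone, 9 rose and 0 fell. The transcription factor Atf3 rose by 1.67 ± 0.16, Ppp1r15a, a phosphatase subunit that restores translation, by 1.01 ± 0.13, the chaperone Hspa5 by 0.81 ± 0.10 from 2279 ± 193 to 4009 ± 338 (SD, n = 4 each), and Calr by 0.52 ± 0.09. Ddit3 rose by 0.94 ± 0.26 (adjusted p = 0.0477), a call that held in 1 of the 8 fits without 1 array (highest adjusted p 0.137, without uninduced replicate 2). The median was 0.29 (camera adjusted p = 3.3e-07, and adjusted p = 0.0121 with an estimated correlation).

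In 3 further lists the camera test passed with the preset correlation and not with an estimated one. Dense-core granule proteins and neuropeptides had 4 of 17 members up, 0 down and 13 not called, and the same 4 adjusted over the list alone. These were Vgf, the peptide-amidating enzyme Pam (0.95 ± 0.09), Ptprn (0.55 ± 0.12) and the granin Scg3 (0.57 ± 0.13). Of the other Pam probe sets 1 rose (0.84), and those at 0.59 and -0.10 did not pass. The median was 0.14 (camera adjusted p = 0.0144, and adjusted p = 0.220 with an estimated correlation). Leaving out 1 array moved this median between 0.02 (without uninduced replicate 2) and 0.24 (without uninduced replicate 4), and to 0.07 without uninduced replicate 3, with the list past the threshold each time. Scg3 passed in 3 of the 8 fits without 1 array (highest adjusted p 0.0700, without induced replicate 1). Targets of REST, a repressor of neuronal genes, had 5 of 34 members up, 1 down and 28 not called; adjusted over the list alone, 6 rose and 1 fell. Vgf, Ptprn and Scg3 are among them, with the synaptotagmin Syt4 (1.01 ± 0.20), while Syp, a synaptic vesicle protein, fell by 0.47 ± 0.09. The median was 0.10 (camera adjusted p = 0.0176, and adjusted p = 0.332 with an estimated correlation), and 7 of its measured members are also in the dense-core granule list. Leaving out 1 array moved this median between 0.07 (without induced replicate 4) and 0.19 (without uninduced replicate 4), and to 0.16 without uninduced replicate 1, also past the threshold each time. Cytosolic ribosomal proteins had 0 of 37 members called in either direction, also 0 adjusted over the list alone, at a median of -0.13 (camera adjusted p = 0.0144, and adjusted p = 0.332 with an estimated correlation). Rpl22 differed by -0.33, Rps15 by -0.26, and Rpl6 and Rpl36 by -0.22 each. The ribosomal call ended with median centring (adjusted p = 0.168) and without induced replicate 4 (adjusted p = 0.0873).

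**Figure D2:**
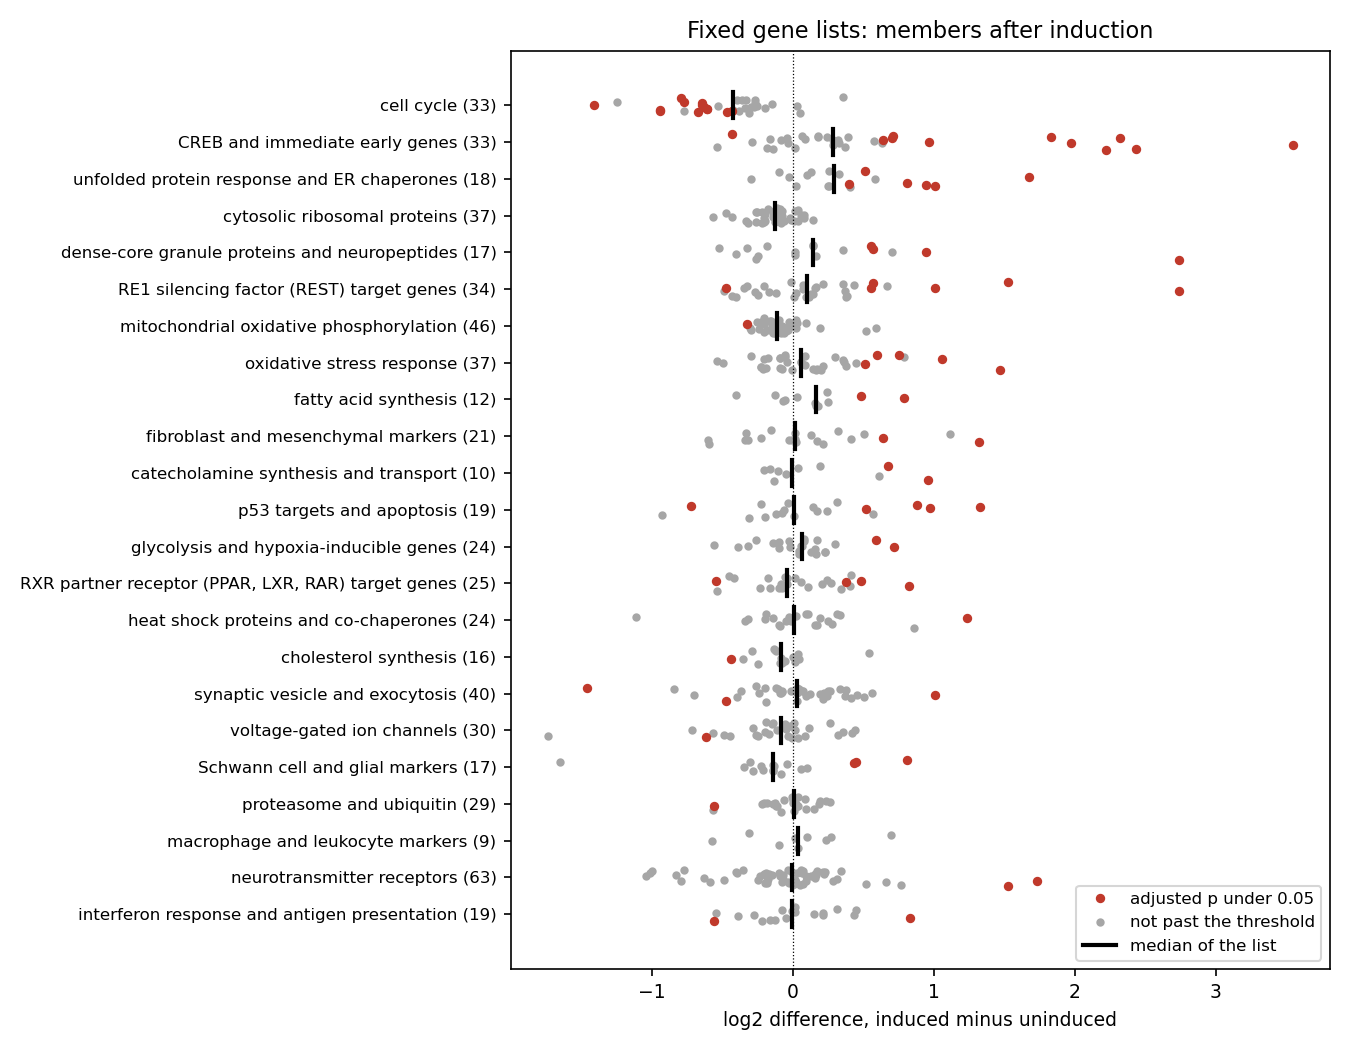
Log2 difference, induced minus uninduced, of each measured member of the tested lists, with the number of members in parentheses; red points passed the test, grey points did not, and black lines are medians. The cell cycle list lies to the left with a median of -0.42, and the immediate early and unfolded protein response lists to the right with medians of 0.29.

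The other 17 lists did not pass camera. The directional test of fry, which asks about a list's own genes and compares them with no others, passed for p53 targets and apoptosis (adjusted p = 0.0060), fatty acid synthesis (0.0448) and glycolysis and hypoxia genes (0.0457) among these. Oxidative stress genes had 5 of 37 members up and 0 down (adjusted over the list alone, 6 up and 2 down; camera adjusted p = 0.0819). The glutathione S-transferases Gstm1, Gstm5 and Gsta4 rose by 1.06 ± 0.09, 1.47 ± 0.13 and 0.76 ± 0.18, and the quinone reductase Nqo1 by 0.60 ± 0.15. Of p53 targets and apoptosis genes 4 of 19 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.123). Gadd45a rose by 1.33 ± 0.15, Mdm2, a ubiquitin ligase for p53, by 0.88 ± 0.11 and the cyclin kinase inhibitor Cdkn1a by 0.98 ± 0.15, and Casp2 fell by 0.72 ± 0.11. Other probe sets of Gadd45a rose by 1.92 and 0.91 while 1 at 0.37 did not pass, and of those of Mdm2 1 rose (1.00) and 1 at 0.04 did not pass. Fatty acid synthesis had 2 of 12 up, 0 down, also adjusted over the list alone (camera adjusted p = 0.0923): Acly by 0.79 ± 0.11 and Scd by 0.48 ± 0.11. Catecholamine synthesis had 2 of 10 up, 0 down, also adjusted over the list alone (camera adjusted p = 0.107). Its median was -0.0030 (-0.066 to 0.17 without 1 array) and its mean 0.18. The members that rose were Gch1 (0.96 ± 0.16) and Spr (0.68 ± 0.08), enzymes of the synthesis of tetrahydrobiopterin, a cofactor of tyrosine hydroxylase. Of heat shock proteins Hspb1 rose by 1.23 ± 0.09, from 11768 ± 1265 to 27581 ± 784 (SD, n = 4 each), 1 of 24 members and the same one adjusted over the list alone; its other probe sets rose by 1.26 and 1.10 or did not pass (0.21). Hspa1l differed by -1.11 (limma adjusted p = 0.0992) at signals of 77.8 uninduced and 33.3 induced, within the background controls. Hspa1a differed by 0.86 (adjusted p = 0.134) and Dnaja1 by 0.33. Of the 24 members 12 were higher and 12 lower (list camera adjusted p = 0.260). Another probe set of Nqo1 did not pass (0.23). In the fits without 1 array, Gsta4 passed in 2 of 8, Scd in 3 and Nqo1 in 4 (highest adjusted p 0.0660, 0.0742 and 0.0794, each without induced replicate 1). Without some arrays the lists themselves passed camera. Oxidative stress did so without induced replicate 3 (adjusted p = 0.0192) or uninduced replicate 3 (0.0457). Fatty acid and catecholamine synthesis did so without uninduced replicate 4 (adjusted p = 0.0466 and 0.0465). Counting the real split, 13, 3 and 5 of the 35 splits of the arrays gave these lists in turn a camera p as small.

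Among metabolic lists, glycolysis and hypoxia genes had 2 of 24 up and 0 down, and adjusted over the list alone 2 up and 2 down (camera adjusted p = 0.207). Eno1 rose by 0.59 ± 0.08 and the glucose transporter Slc2a1 by 0.72 ± 0.18, while their other probe sets did not pass (0.42 and 0.78). Egln3 and Pfkm differed by -0.56 and -0.32 and were not called (limma adjusted p = 0.0624 and 0.0643). Oxidative phosphorylation had 1 of 46 down, 0 adjusted over the list alone, at a median of -0.11 (camera adjusted p = 0.0702); the member was Atp5f1e (fell by 0.32 ± 0.08), and Atp5po and Cox4i2 differed by -0.22 and -0.20. Cholesterol synthesis had 1 of 16 down, also adjusted over the list alone (camera adjusted p = 0.310), Dhcr7 (fell by 0.44 ± 0.11). Its other probe set did not pass (-0.40). Sqle and Fdps differed by -0.35 and -0.24 and Hsd17b7 by 0.54, none of them called. Targets of the RXR partner receptors had 3 of 25 up and 1 down, also adjusted over the list alone (camera adjusted p = 0.260); Acadm rose by 0.82 ± 0.15, Crabp1 by 0.38 ± 0.09 and Lpl fell by 0.54 ± 0.09. That list's median was -0.04, its mean 0.03 and its camera direction up. In the fits without 1 array, Slc2a1 passed in 1 of 8, Atp5f1e and Dhcr7 in 2, and Crabp1 in 3 (highest adjusted p 0.108 for Slc2a1, 0.0796 for Atp5f1e and 0.0956 for Dhcr7, each without uninduced replicate 2, and 0.0731 for Crabp1 without induced replicate 1). The lower oxidative phosphorylation list passed camera without induced replicate 1 (adjusted p = 0.0011), induced replicate 2 (0.0226) or uninduced replicate 4 (8.9e-05), and also with quantile normalization, with no filter, with the mean of a gene's probe sets and with the replicate number as a block. In all it passed in 7 of 21 alternatives (adjusted p from 8.9e-05 to 0.663). Its median ranged from -0.17 to -0.066 without 1 array. Counting the real split, 22 of the 35 splits of the arrays gave this list a camera p as small (the smallest of the others 3.1e-17). These passes therefore cannot be tied to induction.

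Synaptic vesicle genes had 1 of 40 up (Syt4) and 2 down (Syp and Doc2b), also adjusted over the list alone (camera adjusted p = 0.511). Voltage-gated channels had 0 of 30 up and 1 down, also adjusted over the list alone (camera adjusted p = 0.511), the calcium channel subunit Cacna2d1 (fell by 0.62 ± 0.13). Clcn5 differed by -1.73 ± 0.53 (adjusted p = 0.0792). Neurotransmitter receptors had 2 of 63 up and 0 down, and 0 adjusted over the list alone (camera adjusted p = 0.963), Bdkrb2 (1.73 ± 0.47) and Chrnb2 (1.53 ± 0.42), whose uninduced signals of 21.1 and 47.3 lay in the range of the background controls; they passed in 1 and 2 of the 8 fits without 1 array (highest adjusted p 0.141 without induced replicate 3, and 0.126 without induced replicate 2). Cacna2d1 did not pass without uninduced replicate 2 (adjusted p = 0.0518).

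Proteasome genes had 1 of 29 down (Psmb9, by 0.56 ± 0.12) and interferon genes 1 of 19 up (Irf7, 0.83 ± 0.21) and 1 down (Psmb9), both also adjusted over the list alone (camera adjusted p = 0.897 and 0.963). The proteasome median was 0.0077 and its mean -0.03; the interferon median was -0.0077 and its mean 0.01. Of the markers of other cell types, fibroblast markers had 2 of 21 up and 0 down, also adjusted over the list alone, at a median of 0.02 (camera adjusted p = 0.0942); S100a4 rose by 1.32 ± 0.12 and Col5a1 by 0.64 ± 0.10, and Lgals1 differed by 0.21. Schwann cell and glial markers had 3 of 17 up and 0 down, also adjusted over the list alone (Pmp22, Ngfr and Glul by 0.81, 0.45 and 0.43; camera adjusted p = 0.800), with a negative median (-0.14) and mean (-0.11) and an upward camera direction. Leukocyte markers had 0 of 9 called, also 0 adjusted over the list alone (median 0.04, camera adjusted p = 0.897). Adrenal cortex markers were measured for 4 genes only, from Cyp21a1 (-0.39) to Fdx1 (0.34), none called. Other probe sets of Pmp22 and Ngfr differed in the opposite direction and did not pass (-0.37 and -0.33), and another of Irf7 at 0.36 did not pass. In the fits without 1 array, Irf7 and Glul passed in 2 of 8, and Ngfr and Pmp22 in 4 (highest adjusted p 0.121 for Glul and 0.0889 for Ngfr without uninduced replicate 2, 0.109 for Irf7 without induced replicate 2, and 0.0562 for Pmp22 without induced replicate 1). The fibroblast list passed camera without induced replicate 3 (adjusted p = 0.0270). Counting the real split, 12 of the 35 splits of the arrays gave it a camera p as small.

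Other genes named in advance did not pass. The rat Htt probe set differed by 0.20 ± 0.28 (adjusted p = 0.797), with signals of 119 ± 20.9 uninduced and 143 ± 52.6 induced (SD, n = 4 each); it is annotated to the rat gene, so it does not check expression of the human transgene. Bdnf differed by -0.43 ± 0.24, Npy by 0.71 ± 0.43, Syn1 by 0.38 ± 0.15, Snap25 by 0.22 ± 0.13 and Actb by 0.03 ± 0.09. Th, tyrosine hydroxylase, differed by -0.20 ± 0.51 at signals of 70.0 ± 62.9 uninduced and 52.3 ± 28.3 induced (SD, n = 4 each), within the background controls. The sign turned for Htt without induced replicate 2 (-0.0084), for Th without uninduced replicate 4 (0.28) and for Actb without uninduced replicate 2 (-0.03). The log2 ratio of 3' to 5' control signal differed between groups by 0.07 for Gapdh, -0.15 for beta-actin and -0.25 for hexokinase (exact two-sided permutation p = 0.486, 0.829 and 0.257; adjusted over the 3, 0.729, 0.829 and 0.729; n = 4 each).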

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

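Of the tests in this part, those of the beta-actin control and of the immediate early genes against fibroblast markers, RXR partner targets and single arrays, and the decision to count splits of the samples list by list, were chosen after related results had been seen; for the list-by-list counts this was the count of lists passing in other splits. In 13 of 238 groups of 4 arrays, 1 array lay far from the other 3, by a rule that chance meets in about 1 in 20 groups (11.9 here), so the number of such groups gives no reason to look for a shared cause. In uninduced cells, Csrp3 read 135.0 in replicate 1 (the others at most 26.5), Vgf 1184 in replicate 2 (at least 1453), Calr 6392 in replicate 3 (at least 7198), Gstm5 622.9 in replicate 3 (at most 530.4) and Lpl 5766 in replicate 3 (at most 4795). In uninduced replicate 4, Flnc read 371.6 (the others at least 453.5), Atf3 272.5 (at most 192.9), Ndufv2 3041 (at least 4068) and Th 164.1 (at most 41.9). In induced cells, Nqo1 read 904.0 in replicate 1 (at most 684.2), Clcn5 10.5 in replicate 2 (at least 22.3) and Mcm7 1629 in replicate 4 (at least 2024). The 3' beta-actin control read 16020 in induced replicate 3, against 31470 to 36098 on the other 3 induced arrays.

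For that beta-actin control, degraded RNA would lower the 5' signal first and raise the ratio of 3' to 5' signal. The 5' signal on that array was 25489, within the range of the other 7 (22127 to 29402), and the log2 ratio was -0.67 against at least 0.076, which argues against degradation as the cause of the low 3' signal. The ratios of the other controls (Gapdh 0.56 against at most 0.50, hexokinase 1.14 against at most 1.37) leave open whether RNA in that sample was degraded otherwise. The middle beta-actin control was also lowest on that array (28746 against 33191 to 40780), so the low signal was not confined to the 3' probe set, and no biological explanation was tested.

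The higher immediate early genes could in principle come from other cells, from 1 array or from the inducer itself. Fibroblast markers had a median of 0.0185 (bootstrap 95% interval -0.15 to 0.21). The bootstrap drew from the 21 genes, so its interval measures the spread between genes and not between samples. The median ranged from -0.062 to 0.17 without 1 array. With 0.5 of the immediate early list's median at 0.144, inside both ranges, the test cannot decide. Of the 21 markers 12 were higher and 9 lower, and only S100a4 and Col5a1 were called (1.32 and 0.64). All 8 samples are of 1 PC12 line, so fibroblasts would have to be a contamination, which these values leave open. Leaving out any 1 array left the immediate early list past the threshold (highest adjusted p 1.6e-06). An effect of ponasterone through the partner receptors of RXR cannot be told apart from an effect of the transgene. The RXR partner target list had a median of -0.0372 (camera adjusted p = 0.260). It ranged from -0.047 to 0.067 without 1 array and decides nothing. Every induced sample received the inducer, and no line without the transgene is among these samples. An effect of the mutant huntingtin fragment stays among the open explanations, as a hypothesis.

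The lower cell cycle genes might come from the scaling of the arrays or from a trend with signal level. Under the scaling that leaves the smaller fall, the list's median was -0.384 against -0.421 as deposited (adjusted p = 4.5e-10). Of 10000 random gene lists matched on mean signal, the 2.5th percentile of the medians was -0.146 and the lowest -0.228. Both values argue against these explanations as the whole cause, and slower division after induction stays open as a hypothesis, untested here by any count of cells.

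Other splits of the 8 arrays bear on these counts. Of the 35 splits, 1, the real one, called as many as 433 probe sets (the highest of the others called 1). This argues against chance for that count without excluding it, since the share cannot be smaller than 1 of 35. The other splits also mix induced with uninduced arrays, so a real difference widens their spread and lowers their calls. For the number of lists that passed, chance stays open: 8 of 35 splits passed as many as the real 7, and the highest of the others 9. List by list, only the real split (1 of 35) gave a camera p as small for the cell cycle (1.4e-13, the smallest of the others 4.8e-10), immediate early (9.9e-09 and 8.5e-05), unfolded protein response (4.1e-08 and 4.9e-07), dense-core granule (0.0036 and 0.0186) and REST target lists (0.0051 and 0.0095). For ribosomal proteins 7 of 35 splits gave a p as small (0.0034, the smallest of the others 9.3e-06), so chance cannot be excluded. The shares of 1 of 35 have the same limit as above and were not adjusted over the 24 lists tested.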

How the results depend on the processing

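The wording of the source label as a covariate was added after the data were seen; it called 404 probe sets, 398 of them among the 433. Of the 71 called named probe sets 38 passed in each alternative they were tested in, and of 44 others 10 passed somewhere. The direction of all 71 held under the 20 alternatives, which is weak evidence because most of these could not change it. Other filters, other tests, the block and the covariate leave the log2 difference as it was. Leaving out 1 array cannot turn it where the groups do not overlap. The cell cycle, immediate early and unfolded protein response lists passed in all 21 alternatives. Counts moved by over 1.5 times with median centring (230 in all, 167 higher, 63 lower) and without the intensity trend (279, 101 lower). They also did so without replicate 2 of both groups (221, 141 higher, 80 lower) and with an ordinary unmoderated test (282, 112 lower). The count of lower probe sets alone did so without uninduced replicate 2 (119) and without uninduced replicate 3 (112). The cause was not tested, though fewer arrays give less power. With an estimated correlation 4 lists passed in place of 7. Leaving out 1 array gave 313 to 408 probe sets (191 to 244 higher, 112 to 164 lower) and 6 to 10 lists. Replicate numbers did not pair the arrays: same-number correlations of deviations from the group mean were -0.14, 0.06, -0.09 and 0.19, and only number 4 was the best match on both sides. With the replicate number as a block, 367 probe sets passed (218 higher, 149 lower), 351 of them among the 433. Signals within the range of the background controls limit what can be said of the size of a change, for rises and falls.

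Directions reversed only for results past no threshold; the cause was not tested. Over the fits without 1 array, Htt ranged from -0.0084 to 0.40, Th from -0.49 to 0.28, Actb from -0.034 to 0.073 (-0.067 without replicate 2 of both groups) and the log2 beta-actin ratio of 3' to 5' signal from -0.30 to 0.12 (without induced replicate 3). For lists whose camera direction reversed, medians were as follows. Proteasome genes read 0.012 with quantile normalization, 0.0077 with robust moderation, -0.027 without replicate 2 of both groups, and from -0.030 to 0.036 without 1 array (reversed without induced 1 and 2 and uninduced 1 and 4). Receptors read -0.010 with no filter, 0.0079 with quantile normalization, -0.018 without replicate 2 of both groups, and from -0.11 to 0.052 without 1 array (reversed without the same 4 arrays). Interferon genes read 0.0033 with no filter, 0.029 with median centring, -0.0077 with no trend and with the mean of probe sets, and from -0.14 to 0.043 without 1 array (reversed without induced 1, 3 and 4 and uninduced 1 and 2). Schwann cell markers read -0.10 with median centring and -0.13 with the mean of probe sets, and stayed negative without 1 array (-0.18 to -0.017). Leukocyte markers ranged from -0.14 to 0.16 without 1 array (reversed without induced 4 and uninduced 2).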

Other observations

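All genes and families in this and the next paragraph, and the tests on parts of lists further on, were chosen after their values were seen. Among called genes outside the lists above, 12 that rose and 12 that fell were looked up. All 24 passed under quantile normalization and 19 under median centring. No direction changed under either, but median centring shifts every difference by the same amount, too small to turn any of these. Vegfd, a lymphatic growth factor, rose by 1.79 ± 0.16 from 1124 ± 265 to 3852 ± 542 (SD, n = 4 each; limma adjusted p = 2.4e-05). Ctsl, a lysosomal protease, rose by 1.11 ± 0.10, and Nrn1, a neurite-promoting surface protein, by 0.85 ± 0.09. The keratins Krt8 and Krt18 rose by 0.90 ± 0.09 and 1.07 ± 0.12, the membrane-to-actin linkers Ezr and Msn by 0.84 ± 0.13 and 0.89 ± 0.14, Rhob by 0.87 ± 0.13, Anxa1 by 0.88 ± 0.16, Anxa2 by 0.65 ± 0.09, Nes by 0.55 ± 0.12 and the nuclear lamin Lmna by 0.54 ± 0.09. Phox2a, a transcription factor of noradrenergic neurons, fell by 0.70 ± 0.09 from 5765 ± 332 to 3552 ± 331 (SD, n = 4 each; adjusted p = 4.8e-04). Other transcriptional or Notch regulators that fell were Gata3 (by 0.68), Hoxc8 (by 0.76), Nr2f2 (by 1.08), Id1 (by 0.60), Id3 (by 0.42), Dll3 (by 0.97) and Dlk1 (by 0.60). G0s2, an inhibitor of lipolysis, fell by 1.26 ± 0.14, the nucleoside transporter Slc29a1 by 1.06 ± 0.12, the serine synthesis enzyme Psat1 by 0.98 ± 0.13 and Ndufa4l2 by 0.96 ± 0.08. Id3, Dlk1, Gata3 and Hoxc8 passed in 1, 3, 6 and 7 of the 8 fits without 1 array (highest adjusted p 0.108, for Id3). With median centring Nes, Id1, Id3, Hoxc8 and Dlk1 did not pass (adjusted p = 0.152, 0.121, 0.360, 0.0679 and 0.0687).

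Genes grouped by symbol prefix passed in no family with an estimated correlation (lowest camera adjusted p = 0.176 over 10 families). The families were picked for their values, so the counts and medians are a description only. Of annexins 3 of 6 rose and 0 fell (median 0.58), and of dual-specificity phosphatases 2 of 4 rose (Dusp1 and Dusp6). Of mu-class glutathione S-transferases 2 of 4 rose (Gstm1 and Gstm5), of S100 proteins 2 of 6 (S100a10 and S100a4), and of keratins 2 of 6. Of 14-3-3 proteins 1 of 6 rose, and of tubulins 1 of 5 rose and 1 fell. Of histones 2 of 6 fell, of latrophilin receptors 1 of 2, and of Id proteins 2 of 3, with Id2 at 0.42 and not called; with median centring 0 members of these 3 families passed, with medians still negative. No family's median changed sign with quantile normalization or median centring, though the shift from median centring was too small to turn any of them.

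The rise of the REST target list may rest on genes it shares with the dense-core granule list. Without the shared members, 27 genes remained, of which 2 rose and 1 fell, and their camera p was 0.158, while the whole list had 0.0051. Their median was 0.07 against 0.10 for the whole list, a difference within what leaving out 1 array does to the latter (0.07 to 0.19), so the lost call does not show that the shared genes carry the shift, and the hypothesis stays open. A second hypothesis was that the unfolded protein response list rose through the stress-inducible regulators Atf3, Ddit3 and Ppp1r15a alone. Without these 3 genes the remaining 15 still passed (camera p = 4.7e-05, median 0.25, and p = 0.0048 with an estimated correlation), which argues against it.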
